A study of Mus musculus with 2 samples.

How the data were processed

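Gene expression was measured by RNA-seq of total RNA in 2 libraries of mouse splenic γδ T cells, 1 labelled freshly isolated and 1 labelled IL-2 expanded (100 U/ml, 5 days). The deposited table holds whole-number read counts per gene, not normalised, in 1 column per library, with gene symbols and gene spans. Per the submitters' processing notes, the tools named for this series were bcl2fastq 2.18.0.12, STAR 2.6.0, HTSeq 0.6.0 and edgeR 3.28.1, and the builds were mm10 and GRCm38, which are names of the same mouse assembly. The role and settings of each tool, the annotation release, the use of strand and the read length were not given in the sources used here. Without a stated use of strand, counts of a gene and of an overlapping gene on the other strand could not be told apart, and values of overlapping genes are uncertain. STAR and HTSeq are, as background, an aligner and a read counter; with common settings, reads that match several places are not counted, which lowers the counts of genes with near-identical copies.

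Each column was matched to its library by name. The table had 24091 rows, no duplicated symbol and no row without a gene name. Constant genes of the receptor chains and mitochondrially encoded genes were not analysed here. Symbols were compared with a RefSeq annotation of GRCm38.p6. Of the symbols, 23349 matched, and 14471 of these had an identical start, so coordinates are printed as deposited, 1-based, on build GRCm38.

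Libraries were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 (1.056 for the freshly isolated and 0.947 for the expanded library), and counts were divided by the resulting effective library sizes to give CPM. Log2 folds are expanded over freshly isolated with a prior count of 2, and the fold printed for a single gene is a plain ratio of CPM. Counts of genes by size of fold (at least 2-fold, 4-fold or 10-fold) use the log2 folds with the prior count. Genes with a mean of at least 1 CPM over both libraries (11715) were compared. With 1 library per group there is no estimate of the spread between samples, so no p-value for the difference of a gene between the libraries was computed, and genes were counted by size of fold (at least 4-fold). The fold of each gene has an exact 95% interval from the conditional binomial distribution of its counts (Clopper-Pearson), and shares of counts have the same kind of interval. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. At total counts of 20379385 and 22204099, 1 count equals 0.0465 and 0.0476 CPM. Where a library had 0 counts, the fold was computed against a floor of 3 counts in that library and is given as at least that size.

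Before the data were examined, 39 gene lists were fixed from general knowledge of T cells and of other spleen cells, including markers of cells that a sorted fraction could hold. For each list, members with a mean of at least 1 CPM were counted as at least 2-fold higher, at least 2-fold lower or between, and the median log2 fold was set among 10000 random lists of the same size drawn from 20 bins of mean expression. Some genes stand in several lists. Of 21 type 17 genes in the table, 8 are also in another list, as are 11 of 27 chemokine genes and 9 of 24 homing genes. A list median is also given with genes at 0 counts set to their bound where that moves it.

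The genes named in the text follow a rule fixed at the same time. The rule takes the 14 genes furthest up and the 14 furthest down among those with a mean of at least 10 CPM, ranked by the end of the counting interval nearest to no change, leaving out receptor and immunoglobulin segments, mitochondrially encoded genes, ribosomal protein genes, pseudogenes and unnamed gene models. It adds the 2 members furthest up and the 2 furthest down of each list, the 5 genes of highest CPM in each library, and a set of T cell genes always reported. Of that set, Trdc, Tcrg-C1 and Trac were not analysed here, and 2 others are not reported here. The text names a selection of the genes this rule takes. Genes named outside the rule are said to have been chosen after their values were seen.

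The calculation was tested on simulated data for this comparison, with counts of 11731 genes drawn from the means and library sizes of both libraries. All 200 genes changed 8-fold were counted as at least 4-fold in the right direction (100%), 0 unchanged genes were, and 95.6% of counting intervals held the true fold. Of 200 lists of unchanged genes, 3% lay beyond the 2.5th or 97.5th percentile. The simulated counts were Poisson draws, independent between genes, and fewer genes were changed than in the data. The simulation therefore checked the calculation and not how lists of co-regulated genes behave.

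Alternatives fixed before the data were examined were scaling by total count, by DESeq2 1.42.0 size factors, by upper quartiles and by total count without the 50 most abundant genes of each library, prior counts of 0.5 and 10, no filter on low counts, a filter of 5 CPM, and shares without ribosomal protein genes. An alternative added after seeing the data left out genes with under 50% of their 50-base sequences found at no other annotated locus. That share was computed from 1 in 4 of the 50-base sequences of the gene's main transcripts in GENCODE M21, against all transcripts of that annotation, with overlapping genes taken as 1 locus, for 11515 of the compared genes (98.3%), of which 139 were under 50%. Gene families were formed after the data were seen, from symbols that share the letters before their first digit, where at least 10 members were measured. Neighbouring genes were counted as pairs of compared genes next to each other along a chromosome that were both at least 10-fold higher, and set among 10000 permutations within expression bins. Calculations outside R used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.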

Results

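RNA-seq gene counts were analysed for 2 libraries of γδ T cells from mouse spleen, 1 of freshly isolated cells and 1 of cells expanded with interleukin 2 (IL-2). γδ T cells are T lymphocytes whose antigen receptor pairs a γ with a δ chain, where most T cells pair α with β. Per the labels' protocols, the cells were sorted by flow cytometry, and the expansion joined anti-CD3 bound to the plate, anti-CD28 in solution and IL-2 at 100 U/ml over 5 days. The deposited growth and treatment protocols are worded the same for both libraries, and the freshly isolated library was taken as uncultured from its treatment label and the series design, which the protocols do not state. Under that reading, the comparison sets freshly isolated cells against cells that had been activated, cultured and given IL-2 together, and the effect of IL-2 alone was not separable. If both libraries had been cultured, the folds would not include the effect of culture. The total count was 20379385 in the freshly isolated library and 22204099 in the expanded library, over a table of 24091 genes. At least 1 count was present for 15236 genes in the freshly isolated library and for 14148 genes in the expanded library. One count corresponded to 0.0465 CPM (counts per 1000000 of the scaled library size) in the freshly isolated library and 0.0476 CPM in the expanded library, so that 0 counts allowed a level of up to 0.139 and 0.143 CPM, respectively (3 counts). There was 1 library per group, so no difference had a replicate check and none was tested. Intervals given below are exact 95% intervals that cover counting error only.

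The comparison asked which transcripts distinguished expanded from freshly isolated splenic γδ T cells. The expanded library held granzyme transcripts among its most abundant, with higher levels also of transcripts for cell division, cholesterol synthesis, amino acid metabolism and glycolysis. In it, most measured genes of lymphoid homing, the type 17 programme and NK-type receptors were lower. So were most immediate early and tissue dissociation genes and most markers of macrophages and B cells. The summed CPM of the type 17 genes and of the NK-type receptor genes was higher there, however. Of 11715 genes with a mean of at least 1 CPM, 1045 (8.92%) were at least 4-fold higher in the expanded library and 1578 (13.5%) were at least 4-fold lower, while 6164 (52.6%) lay within 2-fold. For all of these 1045 and 1578 genes the counting interval of the fold lay beyond 2-fold. The filter of 1 CPM and the 4-fold cutoff already require enough counts for this, so it is not a further check. With genes under a mean of 5 CPM left out, 992 of 10001 genes were at least 4-fold lower and 811 at least 4-fold higher. The excess of lower genes was then smaller.

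**Figure D1:**
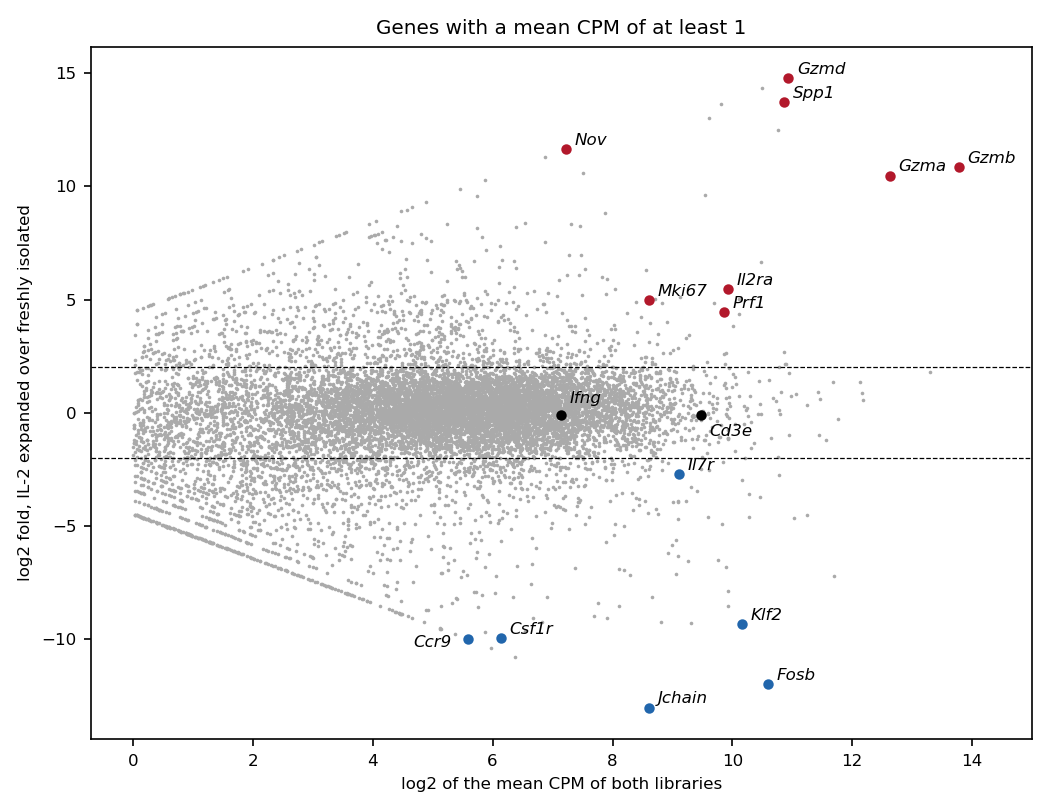
Each point is 1 of the 11715 genes with a mean of at least 1 CPM, with log2 of its mean CPM over both libraries on the x axis and its log2 fold (expanded over freshly isolated, prior count 2) on the y axis. Dashed lines mark 4-fold, and the labelled genes include Gzmb at 10.85 and Fosb at -11.99, while Cd3e lay at -0.09; points along the lower and upper slanted edges are genes with 0 counts in 1 library.

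The most abundant transcripts differed between the libraries. In the freshly isolated library the 5 highest levels belonged to Tnfaip3, an inhibitor of NF-κB signalling, at 6617 CPM, the zinc finger factor Klf6 at 4671 CPM, the actin gene Actb at 4450 CPM, the MHC class I gene H2-K1 at 4247 CPM and the AP-1 subunit Junb at 4020 CPM. In the expanded library they belonged to Gzmb at 28245 CPM, Actb at 15692 CPM, Gzma at 12635 CPM, the actin-binding thymosin gene Tmsb4x at 6483 CPM and the elongation factor gene Eef2 at 5910 CPM. Tnfaip3 was 150-fold lower in the expanded library (interval 141 to 161), at 44.0 CPM. The 10 most abundant genes took 4.40% of the counts in the freshly isolated library (exact Clopper-Pearson 95% interval 4.39 to 4.40) and 8.57% in the expanded library (8.56 to 8.58).

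The gene lists below were fixed before the data were examined. For each list the number of measured members (mean of at least 1 CPM) that were at least 2-fold higher or lower in the expanded library is given, with the median log2 fold (expanded over freshly isolated) and its percentile among 10000 random lists of the same size matched on mean expression. Of 39 lists, 38 had 2 or more measured members, 11 lay above the central 95% of their random lists and 14 below it. The percentiles describe these 2 libraries and are not tests of the conditions.

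**Figure D2:**
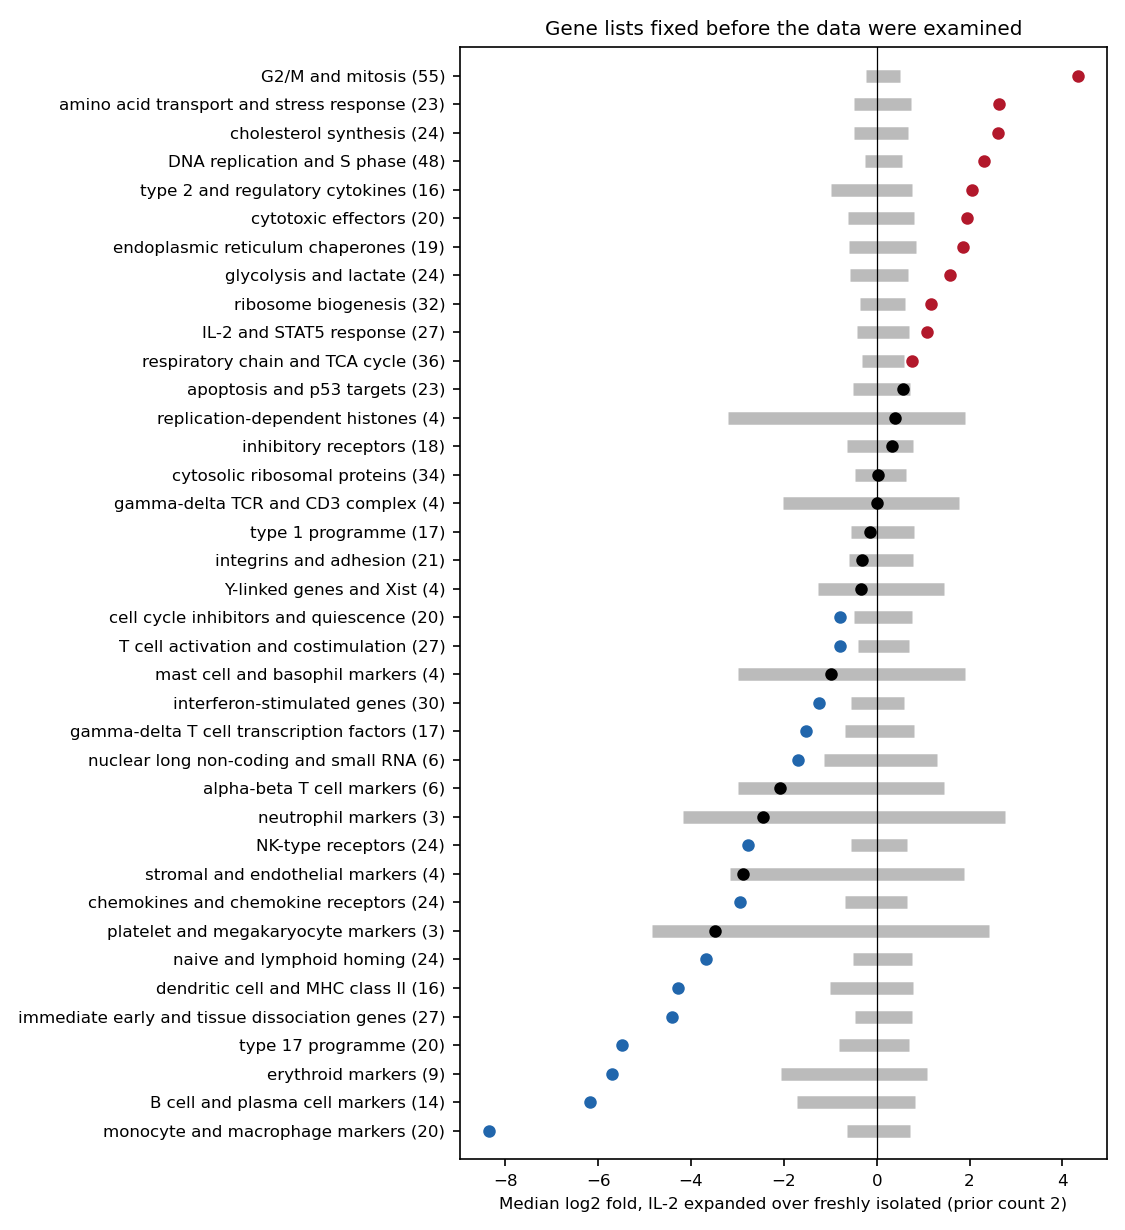
Median log2 fold (expanded over freshly isolated, x axis) of the measured members of each of 38 gene lists, with the number of measured members in parentheses. Grey bars span the central 95% of 10000 expression-matched random lists; red points lie above and blue points below that span, from 4.33 for G2/M and mitosis to -8.34 for monocyte and macrophage markers.

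Transcripts of the CD3 chains, which carry the signal of the T cell receptor, were at similar levels in both libraries. None of the 4 measured members of the γδ receptor and CD3 list was 2-fold apart (median 0.00, percentile 43.9). Cd3e stood at 734 CPM in freshly isolated and 688 CPM in expanded cells, Cd3g at 698 and 743 CPM, Cd3d at 353 and 419 CPM, and Cd247 at 447 and 243 CPM. Cd3g was 1.06-fold higher with the main scaling, whereas the log2 fold of Cd3g was -0.0668 when libraries were scaled by total count. The constant genes of the γ, δ and α receptor chains were not analysed here. Among 6 measured αβ T cell markers, 1 was higher, 3 were lower and 2 lay between (median -2.07, percentile 9.23). Cd4 stood at 9.85 and 0.333 CPM, Cd8a at 0.929 and 9.13 CPM, and Foxp3 at 1.21 and 1.81 CPM. Cd40lg was at 14.2 CPM in freshly isolated cells with 0 counts in expanded cells, at least 99.6-fold lower. Both libraries held Y-linked transcripts, with none of 4 measured genes 2-fold apart (median -0.34, percentile 22.8).

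Markers of other spleen cells were present in the freshly isolated library and low in the expanded library. All 14 measured B cell and plasma cell markers were lower (median -6.16, or -5.89 with genes at 0 counts set to their bound, percentile 0). Jchain, the joining chain of secreted IgM and IgA (chromosome 5, 88519809 to 88527897, build GRCm38), had 784 CPM in the freshly isolated library and 0 counts in the expanded library, at least 5496-fold lower. Cd22 stood at 59.1 and 0.0476 CPM. Of 20 monocyte and macrophage markers, 18 were lower and none higher (median -8.34, or -7.77 with bounds, percentile 0). Over the alternatives in processing the median ranged from -10.34 to -6.14 for the macrophage markers and from -7.43 to -4.40 for the B cell markers, mainly with the prior count, at percentile 0 throughout. The adhesion molecule Vcam1 at 166 CPM and the inhibitory receptor Sirpa at 126 CPM had 0 counts in the expanded library. The receptor for macrophage colony stimulating factor, Csf1r, stood at 141 and 0.0476 CPM and the macrophage perforin-like gene Mpeg1 at 117 and 0.0476 CPM, whereas Cd68 (38.3 and 20.7 CPM) and Hmox1 (119 and 63.0 CPM) were under 2-fold apart. The iron exporter Slc40a1 (97.9 CPM) and the NADPH oxidase subunit Cybb (82.5 CPM) in freshly isolated cells also had 0 counts in the expanded library.

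Of 16 dendritic cell and MHC class II genes, 13 were lower and 1 was higher (median -4.28, percentile 0), among them H2-Aa at 227 and 0.285 CPM, with Batf3 higher at 3.21 and 12.1 CPM. Of 9 erythroid markers, 7 were lower and 2 higher (median -5.70, or -5.07 with bounds, range -7.68 to -3.48 over the alternatives, percentile 0). The β-globin gene Hbb-bs had 44.8 CPM and 0 counts, and the red cell anion exchanger Slc4a1 had 19.1 CPM and 0 counts. The higher members were Tfrc, the transferrin receptor, and Car2, a carbonic anhydrase, and both genes are also expressed outside red cells. Lists of 3 or 4 measured members lay inside the random span. Of 3 neutrophil markers, 1 was higher and 2 lower (median -2.45, percentile 9.72), and of 3 platelet markers, 1 was higher and 2 lower (median -3.47, percentile 7.49). Without a filter on low counts, which takes in 13 neutrophil and 14 platelet markers, both lists lay below the central 95% of their random lists (percentiles 0.475 and 0.02). Of 4 mast cell and basophil markers, 1 was higher and 2 lower, with a median of -0.99 and a mean of 0.42, which differ in sign (percentile 29.5). Of 4 stromal and endothelial markers, 3 were lower and none higher (median -2.88, percentile 3.91), with the scavenger receptor Stab2 at 11.8 and 0.0951 CPM, and without a filter the median was -0.58 (11 genes, percentile 43.6).

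Granzymes, the serine proteases of cytotoxic granules, were among the genes furthest apart between the libraries. Of 20 cytotoxic effector genes, 14 were higher in the expanded library and 1 was lower (median 1.94, percentile 100). Gzmb (chromosome 14, 56258858 to 56262260, build GRCm38) stood at 15.2 CPM in freshly isolated and 28245 CPM in expanded cells, 1859-fold higher (interval 1668 to 2079). Gzma (chromosome 13, 113093827 to 113100981) stood at 8.78 and 12635 CPM, 1439-fold higher (interval 1248 to 1668). Gzmd had 1 count against 3920 CPM in expanded cells, a ratio of 84369 with an interval from 15142 to 3.33e+06. Gzmg (2898 CPM in expanded cells) and Gzme (1801 CPM) likewise had 1 count in the freshly isolated library, Gzmf (1557 CPM) had 2 and Gzmc (3464 CPM) had 11. The deposited spans of Gzme and Gzmd overlap, as do those of Gzmf and Gzmc, so the division of counts within these pairs was uncertain. The pore-forming protein gene Prf1 was 22.04-fold higher (81.0 and 1786 CPM, interval 21.01 to 23.1). The lower member was Gzmm at 13.01 and 1.86 CPM, and Ctsw (429 and 220 CPM) was just under 2-fold lower.

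**Figure D3:**
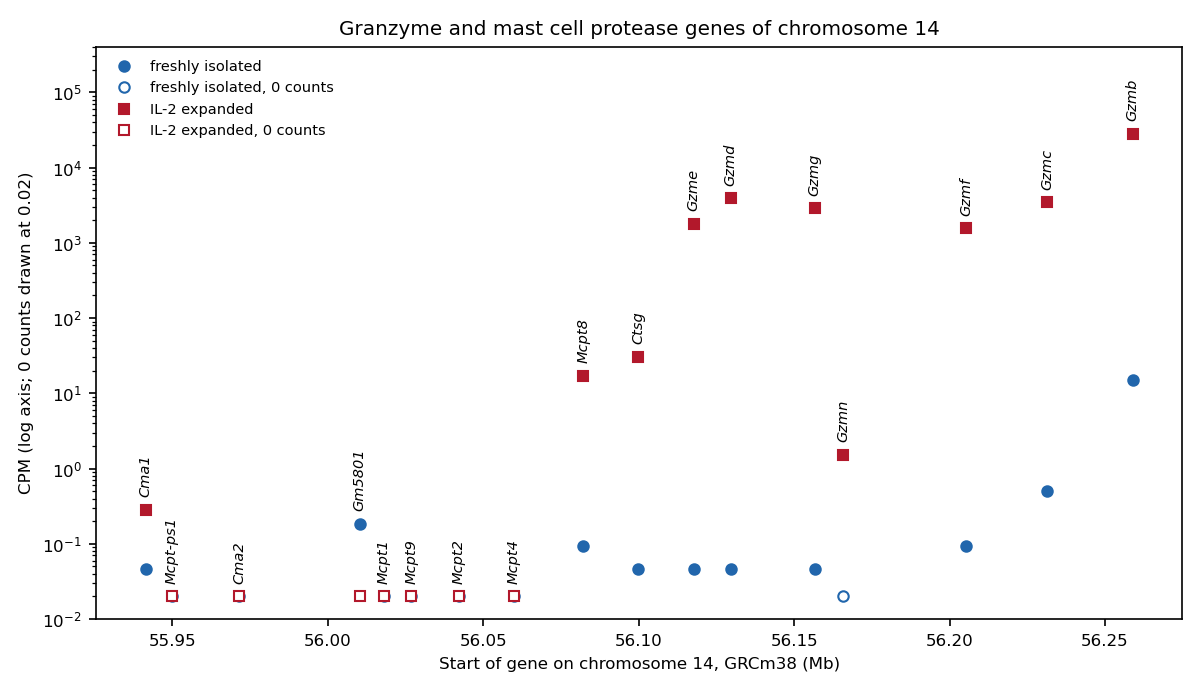
CPM in each library (log axis) of the granzyme and mast cell protease genes along chromosome 14, placed by gene start in build GRCm38 in Mb. Squares are the expanded and circles the freshly isolated library, open symbols at 0.02 mark 0 counts, and Gzmb at the right end stood at 15.2 and 28245 CPM.

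Outside the granzymes, the genes furthest up included secreted proteins and receptors. Spp1, which encodes osteopontin, had 4 counts (0.186 CPM) in the freshly isolated library and 3741 CPM in the expanded library. Nov, a matricellular protein of the CCN family, had 0 counts and 301 CPM, at least 2157-fold higher. Tnfrsf11b, the soluble decoy receptor for RANKL, had 0 counts and 233 CPM, at least 1675-fold higher. The interferon-induced transmembrane gene Ifitm1 was 824-fold higher (1.81 and 1492 CPM, interval 602 to 1158). AA467197 had 3 counts and 365 CPM, and the phosphatase subunit gene Ppp2r2c had 0 counts and 87.5 CPM.

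Transcripts associated with IL-2 receptor and STAT5 signalling were higher as a group. Of 27 measured members, 14 were higher and 2 lower (median 1.09, percentile 99.9). Il2ra, the high-affinity receptor chain (chromosome 2, 11642792 to 11693194), was 43.8-fold higher (43.7 and 1913 CPM, interval 41.0 to 46.7), while Il2rb was 1.89-fold higher (1241 and 2346 CPM). Tnfrsf8, which encodes CD30, had 1 count in the freshly isolated library and 106 CPM in the expanded library. The members lower in the expanded library were Socs3, a feedback inhibitor of cytokine signalling, at 509 and 12.1 CPM, and the kinase Pim1 at 492 and 136 CPM.

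Activation and costimulation genes, by contrast, were more often lower. Of 27 members, 4 were higher and 12 lower (median -0.80, percentile 0.09), and 8 of the 27 are also in another list. Macrophage and B cell markers (medians -8.34 and -6.16) and immediate early and dissociation genes (median -4.42) were lower in the same library. Cd80 (2.79 and 38.4 CPM) and Tfrc (133 and 964 CPM) were the members furthest up. The orphan nuclear receptor Nr4a1, an early target of receptor signalling, was 647-fold lower (1263 and 1.95 CPM, interval 477 to 903), and Tnfrsf25 stood at 24.9 and 0.0476 CPM. The early activation marker Cd69 stood at 1508 and 329 CPM, Cd28 at 1007 and 576 CPM, and Cd44 at 306 and 246 CPM. Among 18 inhibitory receptors, 7 were higher, 5 lower and 6 between (median 0.33, percentile 74.4). Havcr2, which encodes TIM-3, was 44.6-fold higher (11.6 and 516 CPM) and Klrg1 33.4-fold higher (0.604 and 20.2 CPM), whereas Btla (70.9 and 0.761 CPM) and Cd200 (16.5 and 0.476 CPM) were lower. Pdcd1, which encodes PD-1, stood at 73.2 and 120 CPM.

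The transcription factors of γδ T cell subsets were more often lower, with 11 of 17 lower and 2 higher (median -1.53, percentile 0). Their summed CPM was nevertheless higher in the expanded library (1815 in freshly isolated and 2301 in expanded cells). Id2 (349 and 1537 CPM) and Maf (55.3 and 165 CPM) were the higher members. The kinase gene Blk stood at 70.1 and 0.0951 CPM, and Tbx21, which encodes the type 1 factor T-bet, at 106 and 56.9 CPM. Of 20 measured genes of the type 17 programme, 16 were lower and 3 higher (median -5.48, or -5.15 with bounds, percentile 0). Their summed CPM was higher in the expanded library (910 in freshly isolated and 1223 in expanded cells). Il17a had 5.30 CPM in freshly isolated cells and 0 counts in expanded cells, at least 37.1-fold lower. The chemokine receptor Ccr2 was the member furthest up, at 35.9 and 677 CPM. The macrophage markers (median -8.34) and B cell markers (median -6.16) were lower in the same library.

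Genes of the type 1 programme went both ways, with 6 of 17 higher and 6 lower (median -0.15, percentile 17.1). Ifng, which encodes interferon γ, stood at 147 CPM in freshly isolated and 135 CPM in expanded cells. The IL-12 receptor genes Il12rb2 (30.9 and 1084 CPM) and Il12rb1 (49.4 and 465 CPM) were higher, and the chemokine Ccl5 (962 and 13.03 CPM) and its fellow type 1 gene Cxcr3 (107 and 2.71 CPM) were lower. Of 16 type 2 and regulatory cytokine genes, 10 were higher and 4 lower (median 2.06, percentile 100). Il24 had 0 counts and 117 CPM, at least 836-fold higher. Il5 had 1 count in the freshly isolated library and 32.8 CPM in the expanded library. The lower members included the type 2 cytokine gene Il4 (2.28 and 1.05 CPM), the lymphotoxin gene Ltb (334 and 36.6 CPM) and Areg, which encodes amphiregulin (1.90 and 0.333 CPM).

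Genes of naive T cells and lymphoid homing were lower in the expanded library in 23 of 24 members, with none higher (median -3.67, percentile 0). Klf2, a factor that drives expression of homing receptors (chromosome 8, 72319062 to 72321654), was 658-fold lower (2284 and 3.47 CPM, interval 523 to 839). The egress receptor S1pr1 was 647-fold lower (892 and 1.38 CPM) and Ccr7 292-fold lower (806 and 2.76 CPM). Ccr9, a receptor for gut and thymus homing, had 96.0 CPM and 0 counts. The IL-7 receptor gene Il7r stood at 962 and 148 CPM, Cd27 at 321 and 23.8 CPM, and Txnip, at 599 and 342 CPM, was the member under 2-fold lower.

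Of 24 measured genes in the list of chemokines and chemokine receptors, 9 were higher, 13 lower and 2 between (median -2.95, percentile 0). With so few between, the median does not describe a shift of the whole list. The list also holds S1pr1, S1pr4 and S1pr5, which are not chemokine receptors. In a family formed by symbol after the values were seen, 5 of 11 Ccr receptors were higher and 5 lower (median -0.18, percentile 45.4). Ccr1 (0.743 and 62.3 CPM) was the member furthest up, and Ccr9 and S1pr1 were the members furthest down. Of 21 integrin and adhesion genes, 5 were higher, 8 lower and 8 between (median -0.31, percentile 9.62). Ly6a, which encodes Sca-1 (54.7 and 1601 CPM), and Itgav (69.9 and 394 CPM) were higher, and Vcam1, also among the macrophage markers, was furthest down. Of 24 NK-type receptor genes, 18 were lower and 3 higher (median -2.78, percentile 0). Their summed CPM was slightly higher in the expanded library (3344 in freshly isolated and 3655 in expanded cells). Klrk1, which encodes NKG2D, stood at 333 and 44.2 CPM, Klrc2 at 43.2 and 0.381 CPM and Ncr1 at 24.6 and 0.190 CPM, whereas Klra5 (3.34 and 39.3 CPM) and Cd244 (57.3 and 256 CPM) were higher. The macrophage list (median -8.34) and the B cell list (median -6.16) were lower in the same library as most homing and NK-type receptor genes and the lower chemokine genes.

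Genes of cell division were higher in the expanded library. Of 55 genes of G2/M and mitosis, 48 were higher and 1 was lower (median 4.33, percentile 100), and of 48 genes of DNA replication and S phase, 40 were higher and none lower (median 2.32, percentile 100). The proliferation marker Mki67 was 31.3-fold higher (24.1 and 754 CPM, interval 28.7 to 34.2) and the cyclin gene Ccna2 69.3-fold higher (4.32 and 300 CPM, interval 56.5 to 86.0). The ribonucleotide reductase subunit Rrm2 stood at 12.2 and 463 CPM. The lower member was Smc4, a condensin subunit, at 1330 and 607 CPM. Among 20 cell cycle inhibitors and quiescence genes, 4 were higher and 9 lower (median -0.79, percentile 0.23), and 4 of the 20 are also in another list. Macrophage and B cell markers (medians -8.34 and -6.16) and immediate early and dissociation genes (median -4.42) were lower in the same library. Cdkn2a, which encodes p16 and p19Arf, had 3 counts in the freshly isolated library and 55.8 CPM in the expanded library, a ratio of 400.0 with an interval from 136 to 1943. Cdkn2b (0.929 and 83.6 CPM) and Cdkn1a, which encodes p21 (21.9 and 647 CPM), were also higher, whereas Klf4 (431 and 1.19 CPM) and Btg1 (2280 and 189 CPM) were lower. Of 4 measured replication-dependent histones, 1 was higher and 1 lower (median 0.40, percentile 77.7).

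Metabolic and biosynthetic lists were higher as groups. Of 24 cholesterol synthesis genes, 21 were higher and none lower (median 2.62, percentile 100). The squalene epoxidase Sqle was 21.7-fold higher (12.5 and 272 CPM) and the sterol demethylase Cyp51 21.1-fold higher (27.4 and 578 CPM), while Insig1 stood at 64.6 and 93.7 CPM. Of 23 genes of amino acid transport and its stress response, 18 were higher and none lower (median 2.64, percentile 100). Asparagine synthetase, Asns, was 130-fold higher (2.37 and 307 CPM, interval 98.3 to 174), whereas its regulator Atf4 stood at 712 and 563 CPM. Of 24 genes of glycolysis and lactate, 15 were higher and 4 lower (median 1.57, percentile 100). The lactate transporter Slc16a3 stood at 4.18 and 122 CPM and Ldhb at 10.7 and 2.19 CPM. Gapdh had 13.3 and 5.19 CPM, and its value was uncertain because 21.9% of its 50-base sequences occurred at no other annotated locus. Of 36 respiratory chain and TCA cycle genes, 12 were higher, none lower and 24 between (median 0.76, percentile 99.8), with Cox5a at 63.7 and 293 CPM.

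Ribosome biogenesis genes were higher in 21 of 32 cases and lower in none (median 1.18, percentile 100), including Nop16 (16.8 and 88.2 CPM) and Nhp2 (28.4 and 139 CPM). Endoplasmic reticulum chaperones were higher in 12 of 19 cases and lower in 1 (median 1.86, percentile 100). Sdf2l1 (32.2 and 217 CPM) and the disulfide isomerase Pdia6 (126 and 684 CPM) were higher, and Dnajb9 (257 and 30.5 CPM) was lower. Cytosolic ribosomal proteins of the list were not 2-fold apart in 31 of 34 cases, with 3 lower. In a wider set formed by symbol after the values were seen, 54 of 75 measured genes were not 2-fold apart, 19 were lower and 2 higher (median -0.06). The list's median of 0.04 and mean of -0.10 differed in sign (percentile 41.2), and the median was below 0 under 3 of the 4 other scalings (lowest -0.12). Rpl4 stood at 2223 and 3388 CPM. Of 23 apoptosis genes and p53 targets, 10 were higher and 5 lower (median 0.57, percentile 92.8), with Eda2r at 0 counts and 5.38 CPM and the pro-apoptotic gene Bcl2l11 at 166 and 63.6 CPM.

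Immediate early genes and genes known to respond to tissue dissociation were lower in the expanded library in 23 of 27 cases and higher in 2 (median -4.42, percentile 0). The AP-1 subunit Fosb (chromosome 7, 19302696 to 19310045) was 4657-fold lower (3101 and 0.666 CPM, interval 2775 to 8518) and Fos 692-fold lower (2237 and 3.23 CPM, interval 545 to 891). The higher members were Ier3 (4.23 and 48.6 CPM) and the heat shock gene Hsp90aa1 (132 and 326 CPM), of whose 50-base sequences 41.7% occurred at no other annotated locus. Interferon-stimulated genes were lower in 18 of 30 cases and higher in 1 (median -1.23, percentile 0.01). Ifit3 stood at 21.8 and 0.951 CPM and Isg20, the higher member, at 10.5 and 29.2 CPM. Of the 50-base sequences of Ifit3, 47.5% occurred at no other annotated locus. All 6 measured nuclear long non-coding and small RNA genes were lower (median -1.69, percentile 0.52), among them Malat1 at 3062 and 450 CPM and Snhg12 at 102 and 14.7 CPM. The POU domain factor Pou6f1, which belonged to none of the lists, stood at 186 and 0.143 CPM. Macrophage and B cell markers, with the medians of -8.34 and -6.16 given above, were lower in the same library as these groups. Mitochondrially encoded genes were not analysed here.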

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

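The alternative that leaves out genes with few unique sequences was chosen after the data were seen, and the others were fixed before. A change of scaling shifts the log2 folds of a list and of its random lists by nearly the same amount. The position of a list among its random lists could therefore hardly change between scalings, so the scalings do not test that position. The comparisons counted next include them. Over the alternatives, 339 comparisons of gene lists with the main result kept their position inside or outside the central 95% of random lists, with the same sign for each list outside it, and 2 fell outside it where the main list had not. These were the neutrophil markers (median -1.57, percentile 0.475, 13 genes) and the platelet markers (median -1.89, percentile 0.02, 14 genes) with no filter on low counts, where more genes enter each list. Among lists inside it, the median turned with a filter of 5 CPM for mast cell markers (2.80) and histones (-0.15), of which 2 genes each were left, and for cytosolic ribosomal proteins with 3 scalings (lowest -0.12). The size of some medians depended on the prior count or the filter: the macrophage markers ranged from -10.34 to -6.14 over all alternatives, B cell markers from -7.43 to -4.40, erythroid markers from -7.68 to -3.48, type 17 genes from -6.43 to -4.25, dendritic cell genes from -4.81 to -3.21, and type 2 and regulatory cytokine genes from 1.62 to 3.285. The stromal markers moved to -0.58 without a filter. For named genes, 1393 comparisons stayed inside the counting interval of the main value, 204 moved beyond it, and 1 reversed, which was the log2 fold of Cd3g at -0.0668 when scaled by total count (0.09 with TMM). Scaling by total count shifted the log2 fold of all genes by -0.16, and the other scalings by at most 0.08 in size, which is the cause of that reversal. With a filter of 5 CPM, 10001 genes were compared, of which 992 were at least 4-fold lower and 811 at least 4-fold higher. With 1 CPM these were 1578 and 1045 of 11715. The number of lower genes fell by a larger share than the number of genes compared. Part of the excess of lower genes therefore lay among genes under a mean of 5 CPM. The share of higher genes among all at least 4-fold apart was 39.8%, and ranged from 35.1% (total count) to 45.0% (filter of 5 CPM). Without ribosomal protein genes, the 10 most abundant genes took 4.49% of the counts in the freshly isolated and 8.76% in the expanded library, because the total is smaller. No paired analysis was possible because there was 1 library per group, and leaving out a replicate was not possible for the same reason. Depth limited genes with few counts, since 3 counts equal 0.139 and 0.143 CPM.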

Other observations

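The tests of scaling and of neighbouring genes without overlap, the gene families and the single genes in these paragraphs were chosen after the results were seen. Several abundant transcripts outside the lists were higher in the expanded library. The galectin genes Lgals3 and Lgals1 stood at 28.0 and 2827 CPM and at 134 and 1927 CPM in freshly isolated and expanded cells. The metallothionein genes Mt1 (4.46 and 370 CPM) and Mt2 (1.07 and 350 CPM) and the interferon-induced transmembrane genes Ifitm2 (9.38 and 744 CPM) and Ifitm3 (19.5 and 353 CPM) were also higher, although 18 of 30 interferon-stimulated genes were lower. Irf8, best known as a factor of myeloid and B cells, stood at 45.8 and 382 CPM, opposite in direction to the markers of those cells.

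Of 131 gene families formed from symbols, 20 lay above and 17 below the central 95% of random lists, where 6.6 would be expected by chance. Each family median given here, apart from that of the cytosolic ribosomal proteins, is further from 0 than the largest shift between scalings (0.16). The nuclear-encoded mitochondrial ribosomal proteins were higher in 24 of 47 Mrpl genes and 19 of 29 Mrps genes, with none lower (medians 1.02 and 1.13), unlike the cytosolic ribosomal proteins, of which 2 of 75 were higher and 19 lower (median -0.06). Regulatory subunits of the proteasome (Psmd) were higher in 10 of 14 cases with none lower (median 1.27), and nucleoporins (Nup) in 12 of 20 with none lower (median 1.10). Of 13 semaphorins, 7 were higher and 3 lower (median 1.93), with Sema6d at 23.3 and 232 CPM and Sema7a at 8.83 and 100.2 CPM. Of 12 Klf factors, 7 were lower and 2 higher (median -2.10), and 16 of 17 Snora small nucleolar RNA genes were lower. Toll-like receptors were lower in 8 of 10 cases (median -3.72), and macrophage markers (median -8.34) were lower in the same library.

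Most markers of macrophages and B cells were present in the freshly isolated library and much lower in the expanded library, as were 7 of 9 erythroid markers, although the cells had been sorted for γδ T cells. The scalings differed by at most 0.158 on the log2 scale. This argues against the choice among them as the source of medians of -8.34 and -6.16. All of them compare relative levels within a library, so a difference in RNA content per cell would not be seen. A candidate explanation is that the sorted fraction held some macrophages and B cells that were not retained over 5 days of culture: in second lists that share no gene with the first, 82.8% of 29 macrophage genes (24) and 88.2% of 17 B cell genes (15) were at least 4-fold lower, with Ctss at 275 and 21.5 CPM and Apoe at 88.0 and 0.476 CPM. In the opposite direction, the macrophage genes Pltp (11.1 and 23.8 CPM) and Tlr4 (12.8 and 21.9 CPM) were higher in the expanded library, which that explanation does not cover. For red cell precursors the share was 62.5% of 8 genes, with Hemgn higher (2.93 and 16.3 CPM), between the bounds set in advance, so their presence cannot be told apart from single genes of other cells. Of the first lists, 1 of 22 macrophage, 0 of 16 B cell and 1 of 13 erythroid genes were also in another list, Cd68, Hmox1, Cd14 and Cebpb had 20.7, 63.0, 3.47 and 14.1 CPM in expanded cells, and lower expression of such genes by the γδ T cells themselves stays open and untested.

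Some housekeeping genes that are abundant in most cells had low counts in both libraries, such as Gapdh (13.3 and 5.19 CPM) and Eno1 (0.883 and 1.24 CPM), of whose 50-base sequences 21.9% and 43.8% occurred at no other annotated locus. A possible explanation is that reads shared with copies elsewhere were left out of the counts. Across 81 ribosomal protein genes, which are not independent replicates, Spearman's rho between the unique share and CPM was 0.314 in the freshly isolated library (two-sided permutation p = 0.00445) and 0.348 in the expanded library (p = 0.00154), and the 26 genes under 50% unique had median CPM of 26.2 and 16.7 against 103 and 153 for the others. For gene length rho was 0.275 and 0.270 (permutation p = 0.0137 and 0.0155), so both values lay between the bounds set in advance. Adjusted over these 4 tests by the Benjamini-Hochberg method, p was 0.00890 and 0.00616 for the unique share and 0.0155 for gene length in both libraries. The contributions of shared reads and of gene length cannot be told apart here, and no biological explanation was tested.

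Granzyme genes of chromosome 14 and nearby protease genes were higher in the same library: among compared genes, a run of 8 (Mcpt8, Ctsg, Gzme, Gzmd, Gzmg, Gzmf, Gzmc and Gzmb) was at least 10-fold higher, including Mcpt8, a basophil protease gene, at 0.0929 and 17.1 CPM, and Ctsg, which encodes cathepsin G of neutrophils, at 0.0465 and 30.4 CPM. Both had at most 2 counts in the freshly isolated library and were compared because of their level in expanded cells. The adjoining Mcpt1, Mcpt2, Mcpt4, Mcpt9, Cma2 and Mcpt-ps1 had 0 counts in both libraries. Cma1 had 1 and 6 counts, Atp12a on the other side 2 and 5, and Gzmn, within the stretch of the run, 0 and 32. All of these were under a mean of 1 CPM and were not compared, so they do not mark where the higher levels end. Further out, the compared genes Sdr39u1 (22.9 and 59.8 CPM) and Rnf17 (0.976 and 2.38 CPM) were 2.62-fold and 2.44-fold higher. Reads shared between paralogs are unlikely to account for the run as a whole. The median unique share over Gzmb, Gzmc, Gzmd, Gzme, Gzmf, Gzmg and Mcpt8 was 91.7%. It was 100% for Gzmb and Mcpt8 and lower for Gzmd (77.0%), Gzme (78.9%) and Gzmg (82.6%). Overlapping genes were taken as 1 locus, so sequence shared within such a pair counted as unique. Overlapping spans also leave the division between Gzme and Gzmd and between Gzmf and Gzmc uncertain. Genes at least 10-fold higher lay next to each other more often than in permutations in general: with pairs that share their first 3 letters left out, 49 pairs were found against 13 to 30 in the central 95% of 10000 permutations (p = 0.0001, the smallest they can give), and 43 against 12 to 29 without overlapping genes. The same held for lower genes (95 pairs against 44 to 72), so the excess is not particular to genes higher after expansion, and a count over all chromosomes does not bear on the granzyme genes themselves. The reason for their higher levels was not tested and stays open.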
